A study of Homo sapiens with 2 samples.

How the data were processed

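Stranded libraries were prepared from polyadenylated RNA of human IMR90-4 stem cell-derived brain endothelium-like cells that had been lifted from hydrogel channels with trypsin, per the labels' protocols. The samples were 1 library of cells kept static for 1 day and 1 library of cells perfused for 14 days, and both groups were taken from the labels. Per the submitters' processing notes, the tools were HISAT2 (version listed as 1.2.0) and StringTie 1.3.4d with the genome build GRCh38. The annotation release and the filters are not given in the sources used here.

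The deposited table lists 212361 transcripts, each with a coverage and an FPKM value per library and a length, per the file headers. Of these, 206470 carry identifiers of annotated transcripts, all of which were found in GENCODE release 29, and 5891 were assembled transcripts without a gene name. The deposited FPKM is transcript coverage divided by 1 constant per library (24.4 for the static library and 22.8 for the perfused library), as computed from the values. The deposited coverage signal is the mean depth per base of a transcript and is not scaled for library size. The FPKM columns do not sum to a common total.

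Depth was estimated from the deposited coverage signal. Coverage multiplied by length peaked at 300 and 150 bases for transcripts with a single exon, which fits paired reads of 150 bases, so estimated fragments are covered bases divided by 300. These are not counts, since reads shared between transcripts had been divided. The floor used for a value of 0 was 3 fragments, which covers counting error only.

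FPKM values were summed per gene. An assembled transcript was added to a gene when its locus and strand held only that gene or when it overlapped only that gene there, which placed 4257. A further 965 overlapped several genes or none of several in their locus, and 669 lay in loci without an annotated gene, and both kinds were left out. The transcripts left out held 2.82% of the static FPKM and 3.07% of the perfused FPKM. A gene was uncertain when crediting it with transcripts that overlapped it and other genes, in either library or both, could lose its 2-fold call. It was also called uncertain when the total of a locus shared with other genes did not pass 2-fold the same way. Genes of the Y chromosome and inactivation transcripts of the X chromosome were left out. Gene symbols are those of the deposited table.

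The difference between the libraries is log2(perfused FPKM + 1) minus log2(static FPKM + 1), which understates the change of low genes. Genes were kept where the higher library reached 1 FPKM. With 1 library per group no test was possible, so a fixed rule of size (2-fold on that scale) was used, and each gene list's median was ranked among 10000 random lists of the same size, whose members were drawn from 20 bins of mean expression. A list was called outside when its percentile was under 2.5 or over 97.5. Members under the filter were left out of medians. The rule for named genes had 3 parts: 20 fixed genes; in each list up to 4 members with the largest difference past the filter and 2-fold; and the 10 highest and 10 lowest genes among those with a symbol and at least 5 FPKM in the higher library. Other members named for context are endothelial, epithelial, mitochondrial or pluripotency genes of the fixed lists and were chosen after their values were seen. Some genes that the rule takes are not reported here. The groups, the gene lists, this rule, the thresholds and most alternatives were set before the data were examined.

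The calculation was tested on simulated data from the 14923 kept genes with at least 20 estimated fragments in the static library. Of these, 200 were changed, and counting error alone was added. Of genes changed 3-fold, 82.1% passed the 2-fold rule, of those changed 8-fold 96.9% passed, and of those changed 1.5-fold 0% passed. No unchanged gene passed, which shows counting error to be small for these genes. It says nothing about genes with fewer static fragments, which were not simulated, or about variation between cultures. The list ranking was checked on the measured differences between the 2 libraries, not on simulated ones. There 5.0% of random lists of 20 genes fell outside the central 95%, a share that the ranking itself sets. Of such lists raised 1.5-fold, 90.0% lay above it. This check says nothing about lists whose genes vary together.

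The alternatives set beforehand were pseudocounts of 0.1 and 5, no filter and a filter at 5, rescaling both libraries to a common total (TPM), scaling by the median ratio of the libraries, rescaling without mitochondrial genes, the highest transcript in place of the sum, annotated transcripts alone, coverage in place of FPKM, a threshold of 4-fold and list means. Added after the data were seen were covered bases (coverage times length, as a share of the library) in place of FPKM, totals of all transcripts of a locus and strand, protein-coding genes alone, and uncertain genes left out. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.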

Results

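Polyadenylated RNA was sequenced from brain endothelium-like cells derived from IMR90-4, an established human induced pluripotent stem cell line. The cells had been seeded into channels in gelatin hydrogels. A single library came from channels kept for 1 day without flow (the static library), and a single library came from channels perfused for 14 days (the perfused library). With 1 library per condition no difference has a replicate check, so no p-value is given across genes. The days in the channel and the flow differ together, so a difference between the libraries cannot be assigned to either. The deposited table held 18.6 gigabases of transcript coverage for the static library and 17.3 gigabases for the perfused library, which corresponds to about 61900000 and 57700000 estimated fragments of 300 sequenced bases. At this depth 1 FPKM for a transcript of 2 kb rested on an estimated 162 and 152 fragments. Mitochondrial transcripts took 5.21% of the static bases and 7.37% of the perfused bases. Gene positions are on GRCh38.

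The question here was how gene expression differed between cells after 1 day without flow and cells after 14 days with flow, the conditions that the labels give. As lists, genes of the pluripotent state, of proliferation, of glycolysis and of the hypoxia response were lower in the perfused library. Lists of stratified epithelium, lysosome and drug metabolism genes were higher by their medians. Of 20 drug metabolism genes, however, 7 were at least 2-fold higher, 2 lower and 11 within 2-fold. LIN28A, an RNA-binding protein of pluripotent cells (ENSG00000131914, chromosome 1, 26410778 to 26429722), was at 220.8 FPKM in the static library and 0.590 in the perfused library. S100A9, a calcium-binding protein (ENSG00000163220, chromosome 1, 153357854 to 153361027), was at 0.252 and 271.7 FPKM. Of 30 endothelial identity genes 19 were under 1 FPKM in both libraries, and the other 11 went both ways, with 5 at least 2-fold lower, such as CDH5, and 3 at least 2-fold higher, such as S1PR1. Epithelial transcripts were abundant in both libraries. Of 15312 genes that reached 1 FPKM in a library, 1382 were at least 2-fold higher and 1622 at least 2-fold lower in the perfused library on the log2(FPKM + 1) scale, and 12308 lay within 2-fold. With both libraries rescaled to a common total the counts were 1714 and 2867, so that 37.4% of calls were higher in place of 46.0%. Among protein-coding genes, 1142 were higher and 1407 lower. The counts at 4-fold were 292 and 293. Calls for 140 of the higher and 159 of the lower genes depended on reads that overlapping or neighbouring genes could own.

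Of the 41 gene lists fixed before the data were examined, 7 had a median change above the central 95% of random lists matched on expression, 12 had one below it and 22 lay within it. About 2.05 lists would fall outside by chance if the genes within each list varied independently. The random lists draw each gene separately, so a list whose genes vary together can fall outside more often. Several lists also share members. These percentiles describe the 2 libraries and carry no replicate error. The random lists are not matched on gene length or GC content, with which the differences varied. The median difference was 0.17 in the shortest of 10 length bins and -0.28 in the longest. It was -0.07 in the lowest of 10 GC bins and 0.18 in the highest. Only the stratified epithelium, glycolysis, hypoxia and cell cycle lists were corrected for this. For the others, such as oxidative phosphorylation, its share was not tested.

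**Figure D1:**
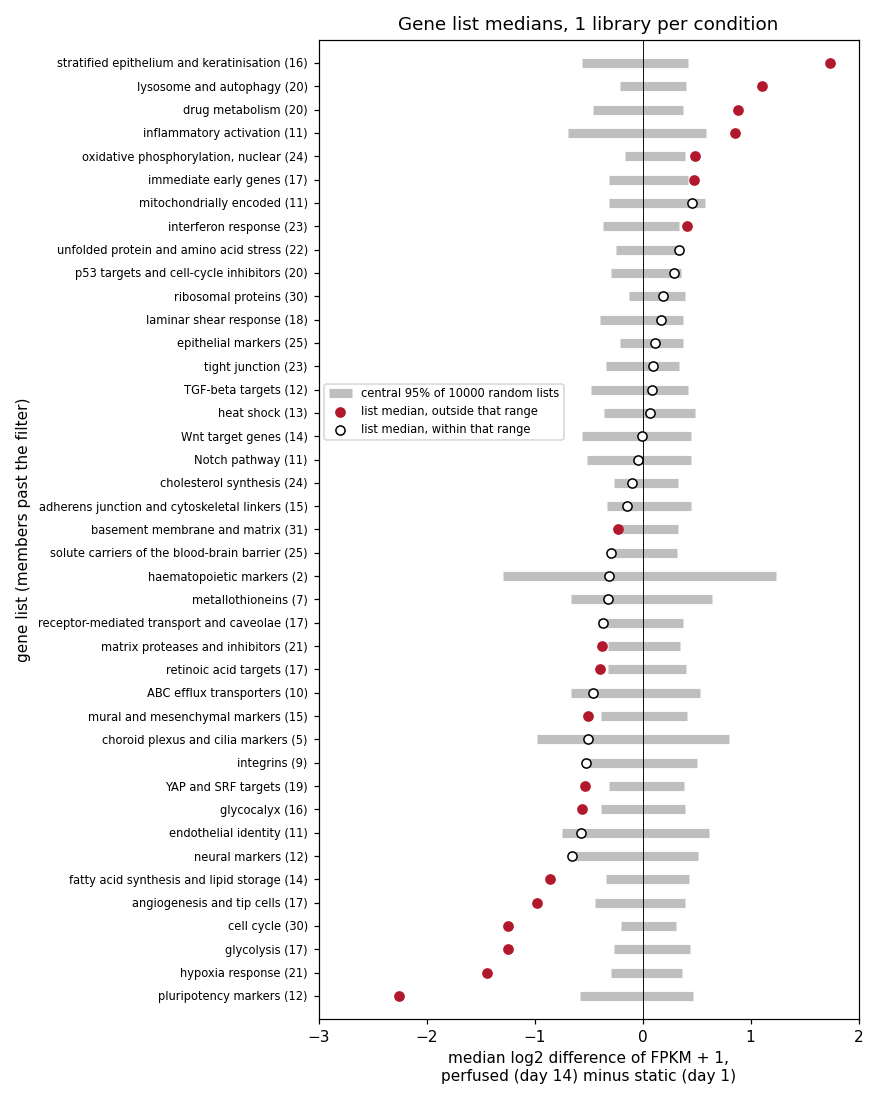
Median log2 difference (perfused minus static, FPKM + 1) of each of the 41 gene lists, as points, with the central 95% of 10000 random lists of like expression as grey bars; the number of members past the filter follows each name. Pluripotency markers lie lowest at -2.26 and stratified epithelium genes highest at 1.74, while the endothelial identity (-0.57) and tight junction (0.10) lists lie within their bars.

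Most endothelial identity transcripts were scarce, and 11 of the 30 genes of this list reached 1 FPKM in a library, with 3 at least 2-fold higher and 5 at least 2-fold lower in the perfused library. The list's median was -0.57 (percentile 8.60), below the central range in 4 of 15 alternative settings, among them both libraries rescaled to a common total (-0.88), and 0.68 with the highest transcript per gene. CLDN5, the main claudin of brain endothelium (ENSG00000184113, chromosome 22, 19523024 to 19527545), was at 0.0564 FPKM in the static library and 0.0168 in the perfused library, an estimated 10.8 and 3 fragments. PECAM1, an adhesion molecule of endothelial junctions, was at 0.00719 FPKM in the static library and listed at 0 in the perfused library, where 3 fragments would be 0.00578 FPKM on its longest transcript and 0.0821 on its shortest. VWF, the von Willebrand factor, was at 0.206 and 0.110 FPKM, and KDR, the main VEGF receptor, at 0.902 and 0.466. CDH5, the cadherin of endothelial adherens junctions (ENSG00000179776, chromosome 16, 66366622 to 66404786), was at 10.4 FPKM in the static library and 0.0381 in the perfused library (log2 difference -3.45). TEK, the angiopoietin receptor, was at 7.95 and 0.262 FPKM (-2.83) and NOS3, the endothelial nitric oxide synthase, at 3.02 and 0.508 (-1.42), whereas S1PR1, a sphingosine-1-phosphate receptor, was higher at 0.249 and 2.52 FPKM.

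Junction genes went both ways. The tight junction list had 23 of 26 members past the filter, of which 2 were at least 2-fold higher, 5 at least 2-fold lower and 16 within 2-fold. Its median (0.10, percentile 69.9) and its mean (-0.17) differed in sign. OCLN (occludin) was at 7.24 and 4.57 FPKM and TJP1 (the scaffold protein ZO-1) at 19.6 and 13.5. Among the claudins, CLDN6 was higher at 67.4 and 176.0 FPKM (1.37) and CLDN1 at 0.287 and 3.14 (1.69), while CLDN10 was lower at 9.50 and 0.748 (-2.59). JAM3 differed by -1.46, and the call for MAGI1 (-2.29) was lost when all transcripts of its locus were summed (-0.49). In the adherens junction list, with a median of -0.15 (percentile 12.5) and a mean of -0.56 that lay below the central range of random means, CDH1 (E-cadherin) was at 81.3 and 93.3 FPKM. The list's 5 lower members out of 15 included VCL (vinculin, -2.09) and MSN (moesin, -1.70), and NECTIN1 was its only higher member (1.21).

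Among transporter genes past 2-fold, more were lower than higher. The lower and higher counts were 2 and 1 for ABC efflux transporters, 5 and 1 for solute carriers and 4 and 0 for receptor-mediated transport. Among all genes the split was closer to even (1622 lower and 1382 higher). Each transporter list's median lay within the central range in the main setting. ABCG2, the breast cancer resistance protein (ENSG00000118777, chromosome 4, 88090264 to 88231322), was at 16.7 FPKM in the static library and 0.572 in the perfused library (-3.50). ABCB1, which encodes P-glycoprotein, was below the filter at 0.900 and 0.196 FPKM, an estimated 256 and 38.7 fragments. ABCC1 was at 19.9 and 13.6 FPKM. Of the 10 ABC efflux transporters past the filter, ABCG2 and ABCA1 (-1.38) were at least 2-fold lower and ABCA2 (1.301 and 8.18 FPKM) at least 2-fold higher, with a list median of -0.46 (percentile 10.6). SLC2A1, the glucose transporter of the blood-brain barrier, was at 171.6 and 150.4 FPKM. Of 25 solute carriers past the filter, 5 were at least 2-fold lower, among them SLC7A3 (-2.56), SLC38A5 (-2.09), SLC2A3 (-1.58) and SLC29A1 (-1.34), and 1 was at least 2-fold higher. Their median was -0.30 (percentile 3.41), and it lay below the central range with the filter at 5 FPKM (-0.49), without a filter, with the highest transcript per gene and as a mean. The list for receptor-mediated transport and caveolae had a median of -0.37 (percentile 4.27), and 4 of its 17 members were at least 2-fold lower, among them IGF1R (-2.03), CAVIN1 (-1.79) and LRP1 (-1.20). It lay below the central range in 7 of 15 alternative settings. LEPR (-1.13) lost its call with locus totals (-0.67).

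**Figure D2:**
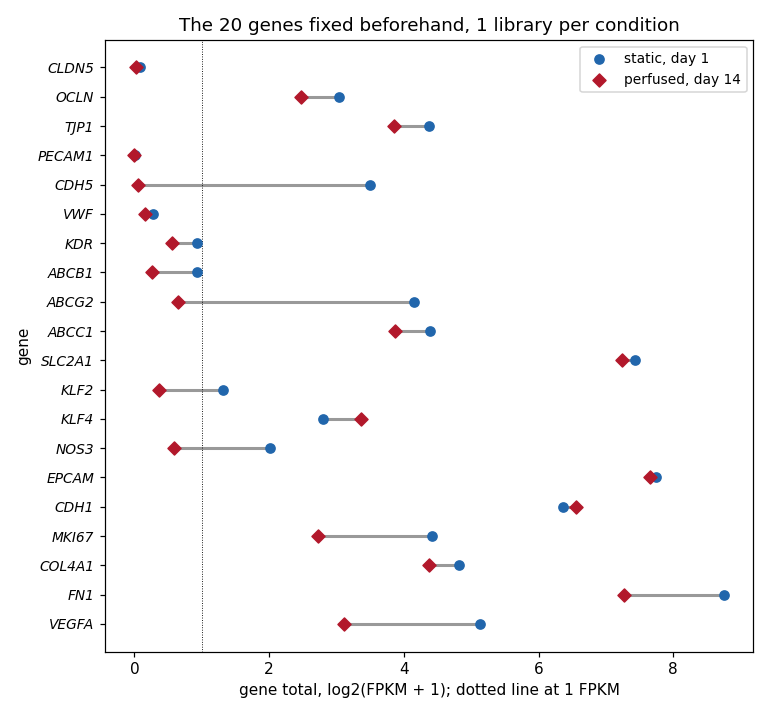
Gene totals, as log2(FPKM + 1), of the 20 genes fixed beforehand in the static library (circles) and the perfused library (diamonds), 1 library each; the dotted line marks 1 FPKM. CLDN5, PECAM1, VWF, KDR and ABCB1 lie below 1 FPKM in both libraries, and CDH5 and ABCG2 are separated by log2 differences of -3.45 and -3.50.

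Genes of the laminar shear response, chosen for their known response to flow in endothelium, did not stand apart as a list (median 0.17, percentile 81.8), except with the highest transcript per gene (0.55). KLF2, a transcription factor induced by shear, was at 1.495 and 0.292 FPKM, and KLF4, a related factor, at 5.93 and 9.31. The 4 members at least 2-fold higher included CYP1B1 (2.90), ASS1, an enzyme of arginine synthesis (2.48), and NQO1, a quinone reductase (2.33). NOS3 and HEY1 (-1.55) were at least 2-fold lower, although HEY1 was at -0.52 with the highest transcript. Genes of angiogenesis and tip cells were lower, with 8 of 17 members at least 2-fold lower and 3 higher (median -0.98, percentile 0). The vascular growth factor VEGFA was at 34.1 and 7.63 FPKM (-2.03), NRP2 at 53.9 and 7.45 (-2.70) and PGF at 10.7 and 1.01 (-2.55), and APLN differed by -1.89.

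Proliferation genes were lower together. Of the 30 cell cycle genes, 23 were at least 2-fold lower and none at least 2-fold higher (median -1.24, percentile 0). MKI67, a marker of dividing cells, was at 20.4 FPKM in the static library and 5.61 in the perfused library (-1.69), and the replication helicase subunit MCM2 was at 57.4 and 15.6 (-1.81). BUB1B (-1.80) and BUB1 (-1.73), of the spindle checkpoint, were also lower. Among p53 targets and cell-cycle inhibitors, 7 of 20 were at least 2-fold higher and 1 lower. The higher ones included CDKN2A at 4.00 and 23.7 FPKM (2.31), CDKN2B at 4.66 and 26.8 (2.29) and GDF15 (1.44). That list's median (0.29, percentile 94.0) lay within the central range, and above it with the filter at 5 FPKM, with annotated transcripts alone (both 0.41) and as a mean (0.56). The call for PHLDA3 (1.43) is uncertain because of reads that other genes could own.

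Pluripotency markers were lower, in parallel with the cell cycle list. Of 12 members past the filter 11 were at least 2-fold lower (median -2.26, percentile 0). LIN28A differed by -7.12, DPPA4 was at 26.9 and 0.518 FPKM (-4.20) and SALL4 at 25.04 and 0.775 (-3.87). POU5F1, which encodes the pluripotency factor OCT4, was at 15.2 FPKM in the static library, an estimated 1736 fragments, and listed at 0 in the perfused library. LIN28A, DPPA4, SALL4 and POU5F1 passed the filter in the static library alone and so could not have come out 2-fold higher. SOX2, at 5.07 and 3.19 FPKM, was the only member past the filter within 2-fold.

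Energy metabolism genes differed by pathway. Of 17 glycolysis genes, 10 were at least 2-fold lower and none at least 2-fold higher (median -1.25, percentile 0). The glycolytic enzymes ENO2 (90.4 and 5.37 FPKM, -3.84), HK2 (19.8 and 1.43, -3.10), LDHA (168.3 and 25.2, -2.69) and GPI (268.0 and 79.4, -1.74) gave the largest differences. Hypoxia response genes had a median of -1.44 (percentile 0), with 12 of 21 at least 2-fold lower, including PFKFB3 (-2.46), ANKRD37 (-2.34) and the collagen prolyl hydroxylase P4HA1 (-2.27); 4 members are also in the glycolysis list. Nuclear genes of oxidative phosphorylation were slightly higher as a list (median 0.48, percentile 99.5), but only SDHC (1.57) and NDUFS1 (-1.18) among 24 passed the 2-fold rule, and both fell within it with covered bases in place of FPKM (0.28 and -0.15). Fatty acid synthesis and lipid storage genes had a median of -0.85 (percentile 0), with ELOVL6 (-2.94) and the desaturase SCD (-1.94) lower and CPT1A, of mitochondrial fatty acid import (3.99), and ACSL1 (3.46) higher. Its mean was -0.25, within the central range of random means. The cholesterol synthesis list had a median of -0.10 (percentile 17.4), with 1 of 24 members at least 2-fold higher, MVK (1.25), and 2 at least 2-fold lower.

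Mitochondrially encoded genes had a median of 0.45 (percentile 92.5), above the central range in 3 of 14 settings, and MT-CO1 was at 5606 and 9387 FPKM. MT-CO3 was at 0.0369 and 3442 FPKM, the largest log2 difference of any gene (11.70), because an assembled transcript that spans it was credited with reads. The smallest difference was 1.69 when transcripts overlapping it and other genes were credited to it in either library or both. With locus totals it was 1.43. Ribosomal protein genes lay within the central range (0.19, percentile 63.4).

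Lysosome and autophagy genes were higher, 12 of 20 by at least 2-fold and none lower by 2-fold (median 1.10, percentile 100). GABARAPL1, of autophagosomes, was at 14.0 and 112.0 FPKM (2.92), the protease CTSD at 76.7 and 256.6 (1.73) and LAMP1 at 57.0 and 166.3 (1.53). Drug metabolism genes were also higher, 7 of 20 by at least 2-fold and 2 lower (median 0.88, percentile 100). ALDH1A1, a retinaldehyde dehydrogenase, was listed at 0 in the static library and was at 12.0 FPKM in the perfused library, and AKR1C2 was at 0.533 and 10.6 (2.92).

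**Figure D3:**
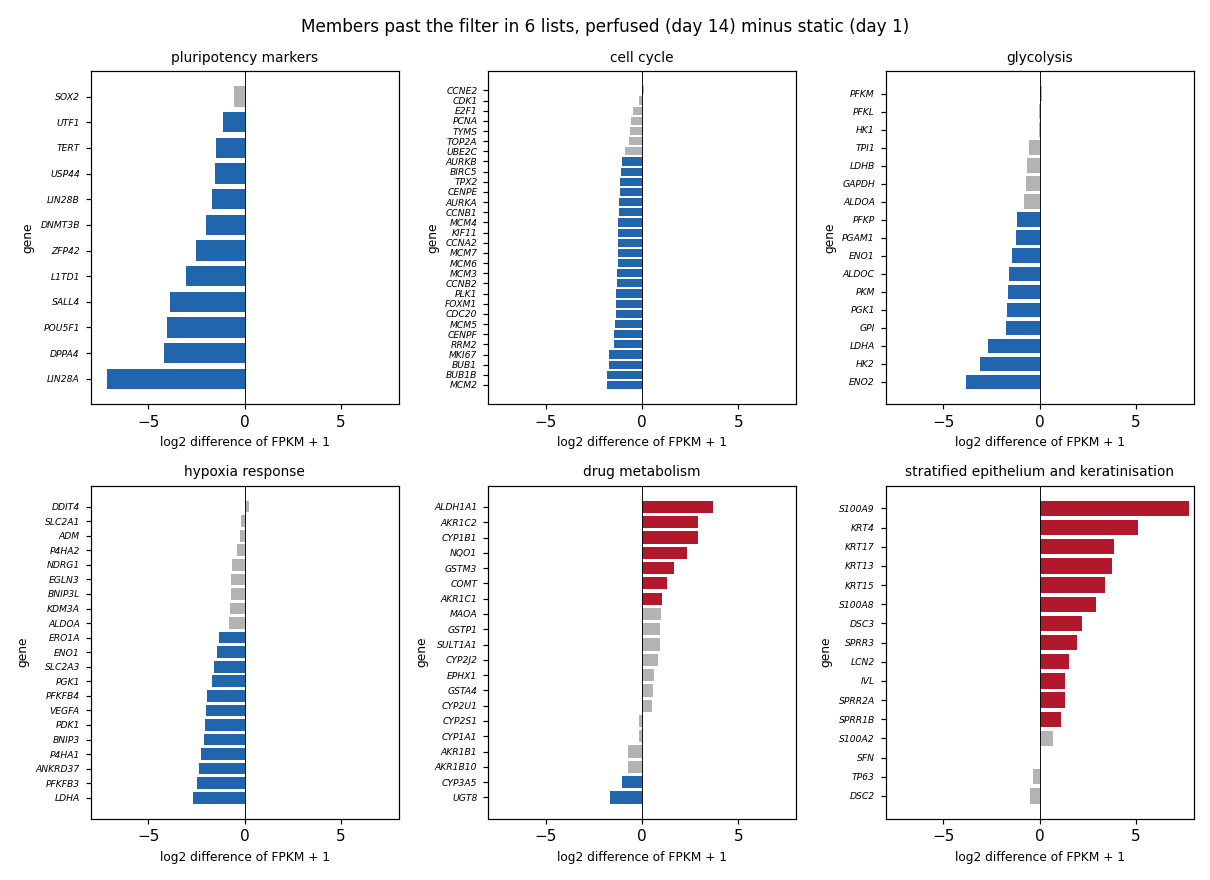
Log2 difference (perfused minus static, FPKM + 1) of each member past the filter in 6 lists, as horizontal bars; blue bars are at least 2-fold lower, red bars at least 2-fold higher and grey bars within 2-fold. No cell cycle or glycolysis bar is red and no stratified epithelium bar is blue.

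Stress and signalling lists had moderate medians. The immediate early genes were higher as a list (0.48, percentile 98.8), with 6 of 17 at least 2-fold higher, including MYC (2.89), JUN (2.30), FOS (1.93) and DUSP1 (1.14); the list lay within the central range with the highest transcript per gene (0.48, percentile 95.2). The inflammatory activation list, with 11 of 22 members past the filter, had 5 at least 2-fold higher (median 0.85, percentile 99.8). The cytokine genes IL1A (0.121 and 13.2 FPKM, 3.66) and IL1B (1.66) and the NF-kappaB inhibitor NFKBIA (24.4 and 77.9 FPKM, 1.63) were among these, as was TNFAIP3 (1.24), which fell to 0.64 with annotated transcripts alone. IL1A and IL1B passed the filter in the perfused library alone and so could not have come out 2-fold lower. In the interferon list 7 of 23 were at least 2-fold higher and 2 lower (0.41, percentile 99.1). IFI44 was listed at 0 in the static library and at 2.93 FPKM in the perfused library, PSMB8 differed by 1.88, IFI6 by 1.68 and BST2 by -1.49. That list stayed above the central range in 12 of 15 alternative settings, and its median was -0.06 with the filter at 5 FPKM.

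The unfolded protein and amino acid stress list had a median of 0.33 (percentile 95.8), with 4 of 22 at least 2-fold higher, DDIT3 (1.51), TRIB3 (1.21), SDF2L1 (1.06) and CHAC1 (1.02). It lay above the central range with covered bases in place of FPKM (0.35, percentile 98.2) and with locus totals (0.35, percentile 97.9). In the heat shock list (0.07, percentile 46.2), HSPB1 (2.29) and DNAJB1 (1.54) were higher. The metallothionein list (-0.32, percentile 17.4) held MT1E (-1.32) and MT1F (1.04) past 2-fold. The lists of TGF-beta targets (0.09, percentile 69.5), Wnt targets (-0.00479, percentile 59.2) and the Notch pathway (-0.04, percentile 45.3) lay within the central range in all settings run. The means of the Wnt (0.21) and Notch (0.40) lists had the opposite sign to their medians. Their largest members included SNAI2 (2.08) and LTBP3 (1.89), APCDD1 (3.32) and FZD4 (-2.85), and JAG2 (2.99) and HES4 (2.01). With locus totals JAG2 was at 2.06. Retinoic acid targets were lower as a list (-0.40, percentile 1.04), with 6 of 17 at least 2-fold lower and 4 higher. HOXB1 (138.2 and 7.94 FPKM, -3.96) and CYP26A1, a retinoic acid hydroxylase (303.8 and 33.5, -3.14), were lower, and CYP26B1, a related hydroxylase, was higher (4.10 and 34.3, 2.79).

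Matrix and adhesion genes moved in both directions. In the list of matrix proteases and inhibitors (median -0.37, percentile 1.37), MMP9 was at 98.4 and 5.15 FPKM (-4.01) and PLAT, the tissue plasminogen activator, at 2.27 and 51.1 (3.99), with 4 of 21 members higher and 4 lower, TIMP1 (-1.99) and MMP2 (-1.56) among them. This list lay within the central range in 8 of 15 alternative settings. The basement membrane and matrix list (median -0.23, mean 0.05, percentile 1.83) lay within it in 7 of 15, with 6 of 31 members higher and 7 lower. FN1 (fibronectin) was at 430.5 and 153.9 FPKM (-1.48), TNC at 38.5 and 1.22 (-4.15), COL1A1 at 163.8 and 40.4 (-1.99), COL3A1 at 15.1 and 179.7 (3.49), SPARC at 39.9 and 445.9 (3.45) and COL4A1 at 27.2 and 19.6 (-0.45). Integrins had a median of -0.52 (percentile 2.88) that lay below the central range in 5 of 15 settings. ITGB6 (2.22) and ITGB4 (2.05) were higher and ITGA2 (-2.12) and ITGA5 (-1.23) lower. Glycocalyx genes were lower as a list (-0.56, percentile 0.190), with PODXL (-4.36), the hyaluronan receptor CD44 (-4.27) and HAS2 (-1.82) lower and SDC1 (2.10) higher. YAP and SRF targets were lower as a list (-0.53, percentile 0.0700), although only 3 of 19 were at least 2-fold lower, VCL, ANKRD1 (-1.99) and TPM1 (-1.22), and ACTG2 was higher (2.43).

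Epithelial markers were abundant in both libraries, with 25 of 26 past the filter (median 0.11, percentile 57.9). EPCAM was at 212.8 and 200.2 FPKM, KRT8 at 2229 and 1092 (-1.03), KRT18 at 1154 and 576.0 and KRT19 at 1079 and 1166 (0.11). ELF3 (1.87) and CLDN6 were at least 2-fold higher and KRT7 at least 2-fold lower (-2.35). Of 28 genes of stratified epithelium and keratinisation, 16 passed the filter and 12 of these were at least 2-fold higher, with none lower by 2-fold (median 1.74, percentile 100). Some of the 16, such as S100A9, KRT4 and KRT13, passed it in the perfused library alone and so could not have come out 2-fold lower. S100A9 differed by 7.77, KRT4 by 5.13 (0.0287 and 35.0 FPKM) and KRT17 by 3.89, and KRT13 was listed at 0 in the static library and at 12.6 FPKM in the perfused library. The list's median ranged from 0.55 to 3.39 over 15 alternative settings and stayed above the central range in each.

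Among markers of other cell types, 15 of 21 mural and mesenchymal and 12 of 22 neural genes reached 1 FPKM in a library. The mural and mesenchymal list had a median of -0.50 (percentile 0.680) but a mean of 0.22, with 4 of 15 members higher, including POSTN (4.06), COL3A1 and DCN (2.18), and 4 lower, including COL1A1. It lay within the central range in 3 of 15 settings. The neural list had a median of -0.66 (percentile 2.61) that lay below the central range in 9 of 15 settings. SOX3 (-4.09), NES (72.0 and 10.9 FPKM, -2.61) and SOX10 (-1.43) were lower and MAP2 (2.38) higher. Only 5 of 17 choroid plexus and cilia markers passed the filter (-0.51, percentile 20.3), with a median below the central range with covered bases in place of FPKM (-0.68). Of these OTX2 was at 1.90 FPKM in the static library and listed at 0 in the perfused library, FOLR1 differed by -1.36 and PIFO by 1.08. Of the haematopoietic markers 2 passed the filter (-0.31, percentile 34.3), neither past 2-fold.

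Among genes of at least 5 FPKM in the higher library, the largest differences after MT-CO3 and S100A9 were those of CFI, complement factor I (0.00513 and 88.8 FPKM, 6.48, but 3.90 with locus totals), WNT10A, a secreted Wnt ligand (ENSG00000135925, chromosome 2, 218880363 to 218899581; 0.289 and 94.96 FPKM, 6.22), and KRT4. SNCG, a synuclein, was at 9.52 and 242.3 FPKM (4.53) and the Wnt ligand WNT6 at 14.2 and 348.5 (4.52). SPRR2F, a small proline-rich protein, was listed at 0 in the static library and at 31.5 FPKM in the perfused library. The difference of DDOST (4.71) was 2.12 with locus totals. Its smallest value was 2.04 with unassigned transcripts of its locus credited to it in either library or both. The value of RF01977 (5.11), a short RNA feature, turned to -0.76 with locus totals. The lowest values after LIN28A were those of CA3, a carbonic anhydrase (63.5 and 0.102 FPKM, -5.87), WFIKKN1 (-5.51, but -2.37 with locus totals), HAPLN1 (-4.97), MYCT1 (-4.91), CD52 (-4.37), PODXL, PRTG (-4.34), CD44 and OLFML3 (-4.22).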

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

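The test of skin keratinocytes in the second pattern was chosen only after the result was seen. Predictions for the others were written down beforehand, although locus totals, which some of them use, were added after the data were seen. Outside the gene totals, 568 assembled loci to which no annotated transcript belongs reached 1 FPKM in a library, and 93 of these were at least 2-fold higher and 89 at least 2-fold lower in the perfused library. Among the 40 such loci with several exons, a strand, a length of at least 500 bases and at least 5 FPKM, the lowest difference was at chromosome 12, 7813862 to 7923009 on the plus strand, at 40.7 FPKM in the static library and 0.178 in the perfused library. That span also holds the NANOG pseudogene NANOGP1 on the same strand and SLC2A14 and SLC2A3 on the opposite strand. Of the 2 other assembled loci there on the plus strand, that at 7813025 to 7919998 was at 29.5 and 39.8 FPKM and that at 7813172 to 7920512 at 10.1 and 0.716. The highest was at chromosome 17, 81510613 to 81512353 on the plus strand, opposite ACTG1, at 0.0130 and 12.7 FPKM. Transcripts of these loci are in none of the gene totals. They could enter locus sums only in the endothelial test below, which added assembled transcripts overlapping a gene on its strand. No explanation was tested for their signals.

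Most endothelial transcripts were low beside high epithelial ones in both libraries, with 19 of 30 endothelial genes under 1 FPKM in both and EPCAM at 212.8 and 200.2 FPKM. Credit of their reads to other transcripts is argued against. Only 5.26% of those 19 genes, which is ECSCR alone, reached 1 FPKM with all locus transcripts and same-strand overlapping assembled transcripts summed. Low depth is argued against as well, since 3 fragments would be at most 0.172 FPKM for any of these genes, taken on the shortest transcript of each. No biological explanation was tested, and whether the cells have an epithelial character or the libraries hold a mixture of cells stays open.

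Stratified epithelium genes were higher in the perfused library, and with the median change of genes of like GC content and length subtracted the list's median was 1.55 (percentile 100), which argues against such bias as the whole cause. Carried-over skin keratinocytes that express KRT5, KRT14 or KRT6A are argued against. The highest of these genes was at 0.0655 FPKM in the perfused library, where KRT4 was at 35.0 and KRT13 at 12.6. The test left out KRT10, which was at 13.1 FPKM in the static library and 55.9 in the perfused library. It therefore cannot decide on skin cells rich in KRT10 instead. No biological explanation was tested, since the design does not separate time, flow and a shift in cell makeup, and these stay open.

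Glycolysis, hypoxia and cell cycle genes were lower in the perfused library. With the GC content and length correction the highest percentile of the 3 lists was 0, with locus totals in place of gene totals it was 0, and with the 4 members shared by the hypoxia and glycolysis lists left out it was 0 for both of these. These values argue against GC content and length bias, against genes shared between the lists and against reads credited to other transcripts of the locus. A biological difference in time or flow, or a loss of proliferating cells with pluripotency transcripts such as LIN28A, stays open and was not tested.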

How the results depend on the processing

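Settings named covered bases, locus totals, protein-coding genes and uncertain genes were chosen after seeing the data. Of the 19 lists outside the central range, 13 stayed on their side of it in all 15 settings run on lists, and 280 of their 285 values kept the direction. The other 6 were matrix proteases, basement membrane, interferon response, fatty acid synthesis, immediate early genes and mural markers. Of 2103 values of the 152 named genes past 2-fold, 47 lay within 2-fold (29 of these with a pseudocount of 5) and 1 changed sign (RF01977, -0.76 with locus totals). The counts of 1382 higher and 1622 lower genes became 542 and 523 with a pseudocount of 5, 945 and 1045 with a filter at 5, 292 and 293 at 4-fold, and 4758 and 7013 with coverage, which is not scaled to FPKM and admits more genes. The count of lower genes was 2867 (1714 higher) with rescaling to a common total (TPM) and 2826 (1917 higher) without mitochondrial genes. Rescaling moves the median of all genes from -0.02 to -0.15 and also admits more genes. Calls were 46.0% higher in the main setting and 37.4% with that rescaling. Leaving out the filter could not change the counts, and no value exists for mitochondrial genes where these were left out. Depth limits mainly genes under 1 FPKM, whose difference the pseudocount understates. Apart from construction as stated, the cause was not tested for the values that follow.

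With a pseudocount of 0.1 the medians were -1.20 (endothelial identity), 1.21 (inflammatory activation), 3.37 (stratified epithelium) and -3.35 (pluripotency). With a pseudocount of 5 they were -0.18 (endothelial identity), -0.48 (angiogenesis), 0.42 (inflammatory activation), 0.20 (interferon), -1.06 (cell cycle), -1.17 (hypoxia), -0.64 (fatty acid synthesis), -0.35 (glycocalyx), 0.51 (drug metabolism), 0.59 (stratified epithelium) and -1.68 (pluripotency). Without a filter they were -0.0270 (endothelial identity), -0.60 (angiogenesis), -0.0875 (matrix proteases), 0.42 (inflammatory activation), 0.64 (drug metabolism), 0.55 (stratified epithelium), -0.18 (mural) and -1.61 (pluripotency). With a filter at 5 they were -2.83 (endothelial identity, 3 genes), -0.13 (ABC efflux), -0.49 (solute carriers), -0.73 (angiogenesis), 1.24 (inflammatory activation), -0.0556 (interferon, reversed), 3.39 (stratified epithelium) and -3.04 (pluripotency). Rescaling to a common total gave -0.58 (receptor-mediated transport), -1.40 (cell cycle) and 2.13 (stratified epithelium), which was 2.23 without mitochondrial genes. The highest transcript gave 0.68 (endothelial identity), 0.55 (shear response), -0.0788 (matrix proteases), 0.00996 (basement membrane, reversed), -1.24 (hypoxia) and -1.03 (glycolysis), and annotated transcripts alone gave 0.00389 (basement membrane, reversed). Coverage gave -0.0779 (tight junction), -1.25 (angiogenesis), 0.64 (interferon), -1.40 (cell cycle), -0.59 (retinoic acid), 2.93 (stratified epithelium), -0.74 (mural) and -3.53 (pluripotency). Means were -0.17 (tight junction), -0.56 (adherens junction), 0.37 (shear response), -0.76 (angiogenesis), -0.18 (matrix proteases), 0.0493 (basement membrane, reversed), -0.25 (fatty acid synthesis), 2.26 (stratified epithelium), 0.22 (mural, reversed) and -2.76 (pluripotency). Covered bases gave -0.60 (receptor-mediated transport), -1.22 (angiogenesis), 0.70 (interferon), 2.03 (stratified epithelium) and -2.77 (pluripotency), and locus totals gave 2.01 (stratified epithelium).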

Other observations

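The families in this part were chosen after their values were seen. Genes of the HOX family, which set position along the body axis, went both ways. HOXB1 (138.2 and 7.94 FPKM) was lower in the perfused library, whereas HOXA5 (22.8 and 118.7 FPKM, 2.33), HOXB8 (1.90 and 25.9, 3.22) and HOXB13 (0.607 and 9.12, 2.65) were higher. Of 25 HOX genes past the filter, 13 were at least 2-fold higher and 3 at least 2-fold lower (median 1.10), and calls for 5 are uncertain because neighbouring HOX genes share a locus. The median was 0.70 without uncertain genes and 0.54 with locus totals, and it stayed above 0 under each scaling run.

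Of 12 Wnt ligand genes past the filter, 9 were at least 2-fold higher in the perfused library and none at least 2-fold lower (median 2.45), and some of these passed it in the perfused library alone. Besides WNT10A and WNT6, WNT11 (0.612 and 14.7 FPKM, 3.28), WNT4 (1.16 and 13.9, 2.79), WNT3 (3.67 and 27.2, 2.60) and WNT5B (4.34 and 28.7, 2.48) were higher. The fixed list of Wnt target genes, which itself includes the ligands WNT7A and WNT7B, had a median of -0.00479 and a mean of 0.21. Of its 14 members past the filter, 4 were at least 2-fold higher and 2 lower. Of 13 S100 genes past the filter, 7 were at least 2-fold higher and 1, whose call is uncertain, lower (median 1.08), with S100A6 at 135.8 and 617.3 FPKM and S100A11 at 577.1 and 1222. The V-type ATPase subunits, which acidify lysosomes, had a median of 0.49 over 24 genes past the filter, and 4 were at least 2-fold higher and 3 lower, the lowest being ATP6V1B1 (8.92 and 0.482 FPKM, -2.74). The medians of the Wnt ligand, S100 and V-type ATPase families were positive under every alternative setting run.

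Insulin-like growth factor binding proteins went both ways, with IGFBP2 at 1752 FPKM in the static library and 262.9 in the perfused library (-2.73), IGFBP5 at 161.4 and 29.3 (-2.42), IGFBP3 at 71.2 and 206.5 (1.52) and IGFBP7 at 3.93 and 32.3 (2.75). Among 9 annexins past the filter, ANXA1 was at 206.6 and 1059 FPKM (2.35) and ANXA6 at 63.7 and 27.3 (-1.19), with a family median of 0.07. Keratins had a median of 0.11 over 11 genes past it, with 5 at least 2-fold higher and 4 lower. Aldo-keto reductases had a median of 0.29 over 7 genes past it, and it turned to -0.25 with the highest transcript per gene and to -0.27 with coverage.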
